A study of Homo sapiens with 8 samples.

How the data were processed

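KHYG1 and NK92 are established human cell lines grown from malignancies of natural killer (NK) cells, lymphocytes that kill other cells without prior priming, and both need interleukin 2 to grow. Per the labels' protocols, each line was infected with a retrovirus made in 293T packaging cells that carried the full-length α isoform of PRDM1 together with GFP, or with the same vector without PRDM1. GFP-positive cells were collected by flow sorting at 48 h, and 60 ng of total RNA per sample was turned into biotin-labelled cRNA and measured on Affymetrix expression arrays, per the labels' protocols. The series holds 8 arrays in 4 groups of 2, empty vector and PRDM1α in each line, and the group and replicate number of every array came from its title. The labels call the 2 arrays of a group biological replicates. They do not say whether these were separate transductions, so the p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

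The deposited values are on a log2 scale, read from the values themselves, which ran from 1.78 to 14.02 with array medians between 6.23 and 6.37. The submitters' processing notes name MAS5, the Affymetrix algorithm that condenses the probes of a probe set into 1 value, with no version. How the logarithm was taken, the scaling between arrays and the reason why the table lists the probe sets it does are not given in the sources used here. The table holds 26126 probe sets, of which 53 are controls. In the platform annotation, 21329 of the others carried 1 gene symbol, 1025 carried several and 3719 carried none, so that 11526 genes were named, and none was named from a probe set with several. For 21317 of those probe sets the symbol was found in a reference table of assembly GRCh38.p14, which changed 0 symbols and was used only for names and for which genes neighbour each other. No genome build was named for the arrays, so no coordinates are given.

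The plan had allowed for linear values, to be tested as log2(value + 32), or for a table already on the log2 scale, to be used as it is. The second case applied, and no pseudocount was added. Each gene was represented by the named probe set with the highest mean over the 8 arrays. Genes were kept where that probe set lay above the 40th percentile of its array in at least 2 of the 8 arrays, which left 9029 genes. All 8 arrays were fitted together with 4 group means in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with an intensity trend), with 4 residual degrees of freedom and 11.4 prior degrees of freedom. Contrasts were PRDM1α minus empty vector in each line, the difference of these contrasts (NK92 minus KHYG1), and NK92 minus KHYG1 under empty vector. An additive fit with line as a covariate and 5 residual degrees of freedom gave the change common to both lines. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, all tests were 2-sided, and standard errors (SE) are those of limma.

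Before the data were examined, 22 gene lists and 6 lists of markers for other cell types were fixed from general knowledge, as were the comparisons, the filter and the rule for naming genes. The 24 lists with at least 3 tested genes were tested with camera at its preset correlation of 0.01, and adjusted p-values of lists are adjusted over those 24 within a comparison. Every list call was repeated with a correlation estimated from the data and with fry, which tests whether the genes of a set move on balance in one direction without comparing them with other genes. None of the list calls passed with the estimated correlation, whose adjusted p is given beside each. These losses cannot be put down to correlated genes alone. With an estimated correlation camera takes the residual degrees of freedom of the fit, here 4 or 5. At the preset correlation it takes a number set by the genes. A loss was therefore likely for any list, and does not by itself show correlated genes. In NK92 the DNA replication list went from a camera adjusted p of 0.00134 to 0.108. Its estimated correlation was −0.0072, below the preset value. Genes named in the text were chosen by rule. In each line and for the common change these were the 10 largest rises and 10 largest falls among genes past the threshold whose PRDM1α arrays all lay on one side of the empty-vector arrays of their line. The rule added the 5 smallest p in each direction for the difference between lines, the 10 largest differences in each direction between the lines, up to 4 members of each list by smallest p, all tested members of the list of known PRDM1 targets and every PRDM1 probe set. Families of genes described in the closing section, 29 in number, were chosen after the values were seen. Genes read by probe sets that end in _x_at, such as XCL1, FXYD2, CALR, CENPA, IDI1, NR4A2, CXCL8 and members of the KIR and IFITM families, can share sequence with relatives and are uncertain.

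The pipeline was tested on simulated arrays with the means and spread of the real 9029 genes, of which 200 were changed by known amounts in one line. In KHYG1, 83% of changes of 0.5 log2 and 100% of changes of 1 log2 were recovered, and 3.68% of the calls were false. In NK92 the recovered shares were 87% and 100%, and 5.08% of the calls were false. No recovered gene had the wrong sign, with 0 in each line. The noise was drawn independently for each gene and array from the spread that limma itself had estimated. A low share of false calls was therefore close to fixed in advance. The simulation checks the code and does not give the error rate of the real arrays.

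Alternatives covered quantile normalization, median centring of each array, values taken back to the linear scale with 1 or 128 added before the logarithm, no filter, a filter at the 60th percentile, the mean of a gene's probe sets, eBayes without the trend or with robust fitting, an adjusted p under 0.1, a 2-fold requirement, each line's arrays fitted alone with 2 residual degrees of freedom, the mean of both lines' contrasts, the replicate number as a block, and each array left out in turn. Overlap between the lines was compared with 100 simulated data sets in which the NK92 changes were shuffled among genes of similar spread in 20 bins. The size of the response in NK92 was set against that in KHYG1 with intervals from 2000 bootstrap resamples of genes. No detection calls were used, and signals near or below the 10th percentile of an array, 3.31 to 3.38, were treated as close to the floor. Sex-linked genes used to tell samples apart were not named. Every column of the table was used.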

Results

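The expression of 9029 genes was compared between cells transduced with PRDM1α and cells transduced with empty vector in 2 malignant human NK cell lines, KHYG1 and NK92, with 2 arrays in each of the 4 groups. PRDM1, also called BLIMP1, is a zinc-finger transcriptional repressor that drives the end stages of lymphocyte differentiation. The comparisons ask which genes change when it is put into malignant NK cells. Across all 26126 probe sets of the table, replicate arrays correlated at r = 0.996 in every group. Arrays of different treatment in a line correlated at 0.991 to 0.993, and arrays of different lines at 0.883 to 0.898. The median SD between replicates fell with signal, from 0.148 log2 for 1211 genes below 6 to 0.0923 between 6 and 8, 0.0608 between 8 and 10, and 0.0460 for 917 genes above 10, so changes of dim genes were measured less precisely.

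The transduced gene was examined first. PRDM1 was read by 3 probe sets, called here brightest, middle and dimmest after their mean over the 8 arrays, and the brightest went against the label. It measured 8.19 ± 0.0095 (SD, n = 2) in KHYG1 with empty vector and 6.21 ± 0.13 in the arrays labelled PRDM1α. The corresponding values in NK92 were 8.82 ± 0.059 and 6.67 ± 0.0040. This probe set was thus 3.94-fold lower in KHYG1 (log2 change −1.98, SE 0.085, limma adjusted p = 1.25e-09) and 4.43-fold lower in NK92 (−2.15, adjusted p = 1.30e-09) in the arrays that should carry the transgene. The middle probe set rose by 0.62 in NK92 (1.54-fold, adjusted p = 0.0120), and its change of 0.12 in KHYG1 did not pass (SE 0.14, adjusted p = 0.648). The dimmest probe set fell by 0.86 on the log2 scale in NK92 (adjusted p = 0.0187) and changed by −0.18 in KHYG1 without passing (adjusted p = 0.645). In NK92 the call of the middle probe set was lost without any single NK92 array (adjusted p from 0.0525 to 0.0742). That of the dimmest was lost without array 1 of empty vector (0.186) or array 2 labelled PRDM1α (0.129). The brightest passed in every such fit. Which part of the PRDM1 transcript each probe set reads is not given in the sources used here, so these values do not show by themselves how much transgene was expressed. Because of them, groups are called the arrays labelled PRDM1α throughout, and every direction given for these arrays rests on those labels.

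**Figure D1:**
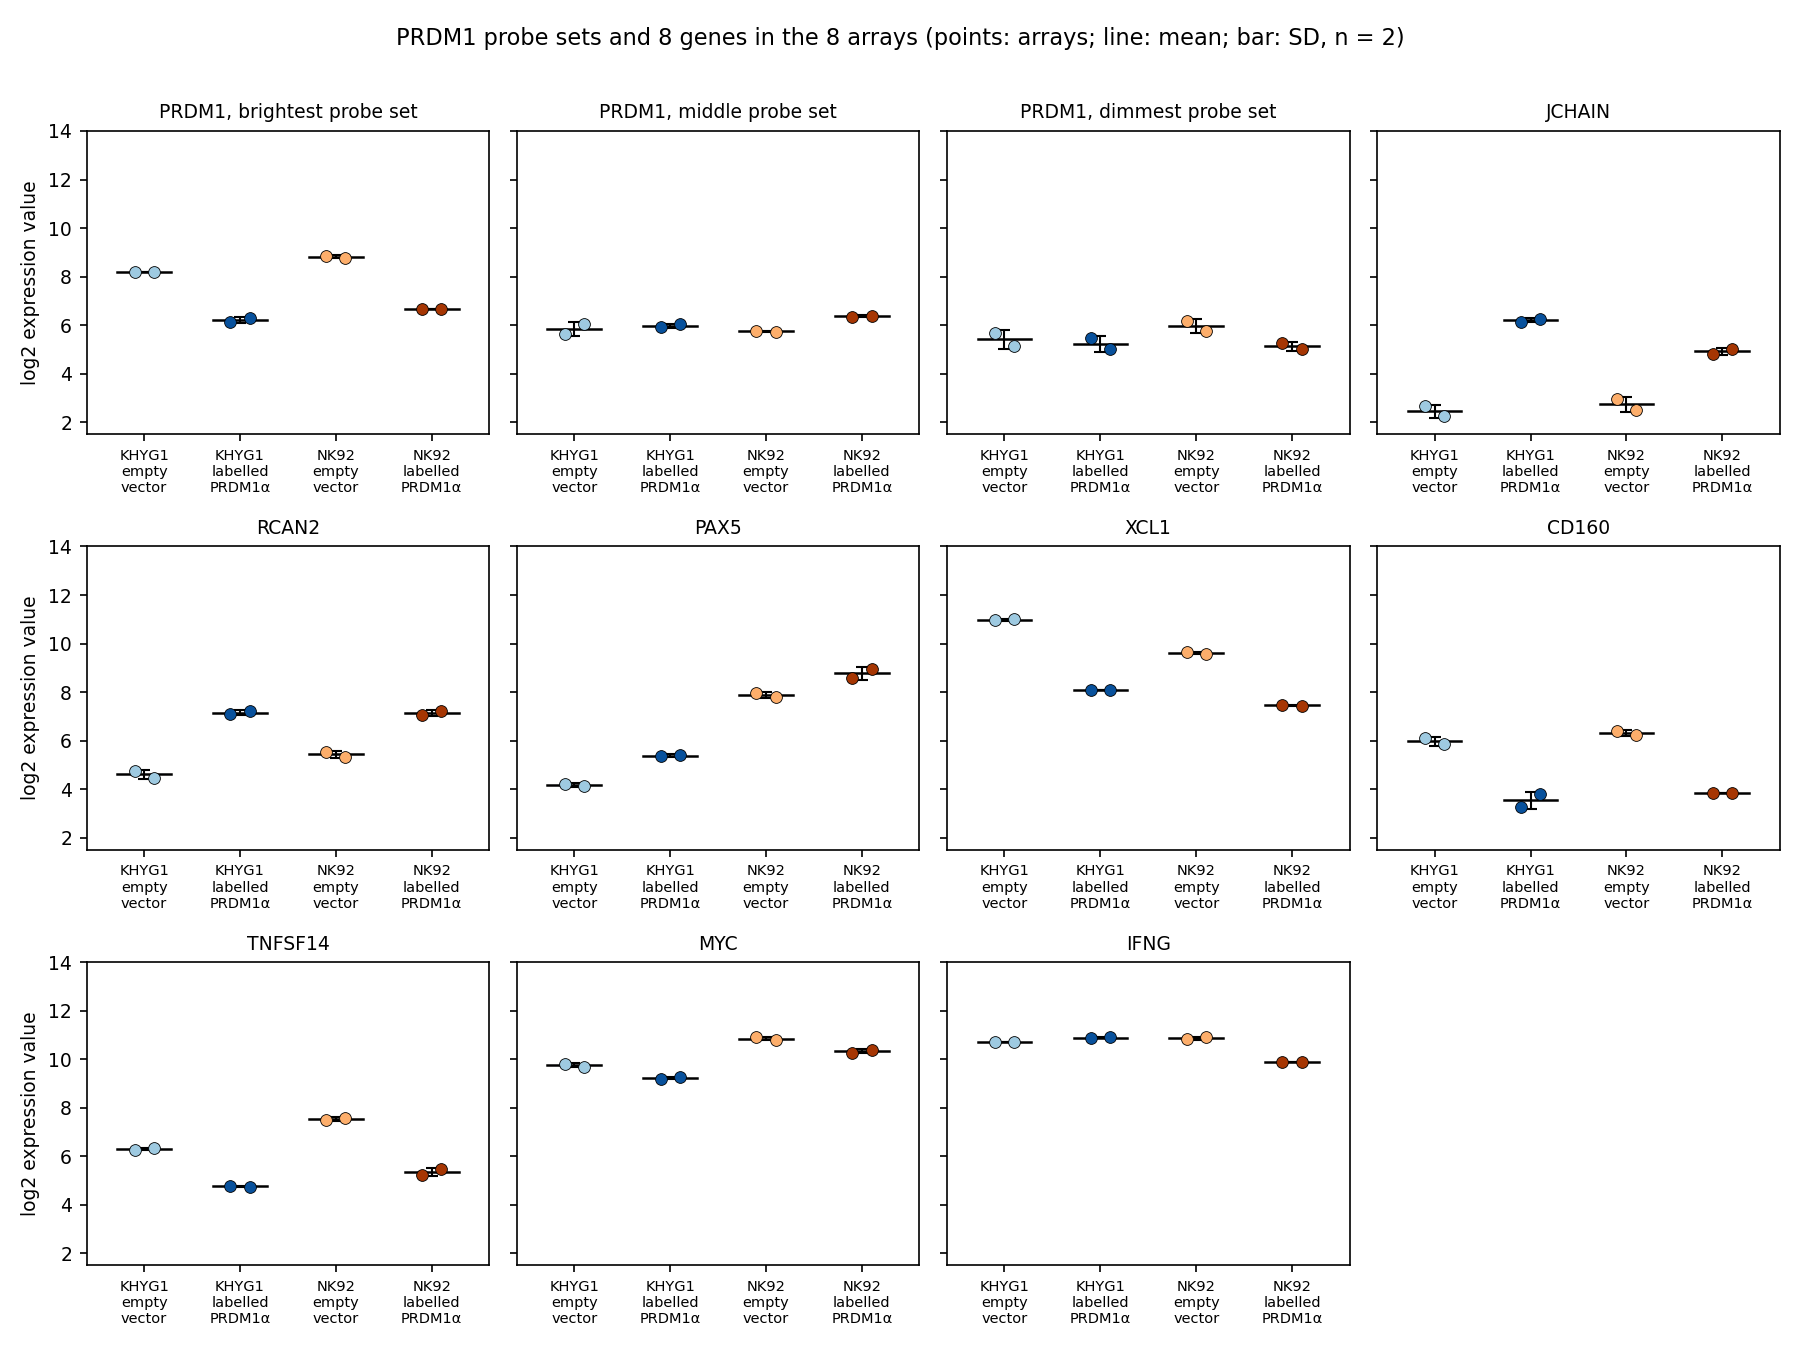
Log2 expression values (vertical axis) of the 3 PRDM1 probe sets and of 8 genes in the 4 groups (horizontal axis); points are arrays, horizontal lines are group means and bars are the SD (n = 2). The brightest PRDM1 probe set drops from 8.19 to 6.21 in KHYG1 and from 8.82 to 6.67 in NK92 in the arrays labelled PRDM1α, while JCHAIN climbs from 2.46 to 6.2 and from 2.73 to 4.93.

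In KHYG1, the largest rise in the arrays labelled PRDM1α was in JCHAIN, the joining chain of polymeric immunoglobulins and a plasma-cell product. It went from 2.46 ± 0.27 to 6.2 ± 0.076 (SD, n = 2), a 13.4-fold rise (log2 change 3.74, SE 0.23, limma adjusted p = 1.49e-08) from a level at percentile 1.27 of all probe sets, so that the size of the rise is uncertain. RCAN2, a regulator of calcineurin signalling, rose 5.85-fold (2.55, SE 0.14, adjusted p = 3.70e-09). XCL1, the chemokine lymphotactin made by activated NK and T cells, fell from 10.97 ± 0.029 to 8.09 ± 0.0098, a 7.39-fold fall (−2.89, SE 0.055, adjusted p = 7.45e-15). Its probe set can share sequence with relatives, so which of them fell is uncertain. The NK receptor CD160 fell 5.40-fold (−2.43, SE 0.19, adjusted p = 1.93e-07) and CCR7, which guides lymphocytes to lymph nodes, fell 5.10-fold (−2.35, SE 0.21, adjusted p = 7.87e-07). Both ended near the floor, CD160 at 3.54 and CCR7 at 3.50, where the 10th percentile of the arrays lay between 3.31 and 3.38, so the sizes of these falls are uncertain as well.

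Further large rises in KHYG1 were in the tyrosine kinase FES (log2 change 2.47), the long non-coding RNA CRNDE (2.18, from a level of 2.58 near the floor), SPP1, which encodes osteopontin (2.01), FGFBP2, a secreted protein of cytotoxic lymphocytes (1.70), the sodium pump regulator FXYD2 (1.66), NBAS (1.63), the semaphorin receptor PLXNA1 (1.48) and GNLY, the pore-forming granule protein granulysin (1.40). Large falls were in the transcription factor BATF3 (−2.02), DENND11 (−1.88), the surface protein SLAMF8 (−1.74), the early response factor EGR4 (−1.72), ADAP1 (−1.56) and TNFSF14, a TNF-family cytokine also called LIGHT (−1.55). By the rule that chose these genes, both arrays labelled PRDM1α lay on one side of both empty-vector arrays for each. In all, 2656 of the 9029 genes passed in KHYG1, 1085 higher and 1571 lower, against 3593 at an unadjusted p under 0.05. The excess of lower genes depended on the scaling of the arrays, with 1442 higher and 1415 lower under quantile normalization and 1352 and 1416 under median centring. At least a 2-fold change was seen in 68 of them, 25 higher and 43 lower.

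Ribosome biogenesis genes fell as a group in the arrays labelled PRDM1α of KHYG1. All 25 tested members of the list fell, and 25 fell when adjusted over the list alone, with a median change of −0.55. RRS1 (−1.0) and NOP16 (−0.99), both needed for the large ribosomal subunit, the nucleolar helicase DDX21 (−0.84) and the nucleolar protein NOLC1 (−0.77) were among them (camera adjusted p = 4.92e-19; adjusted p = 0.0703 with an estimated correlation). In the same arrays the control probe sets for the 5′ part and the middle of 28S ribosomal RNA were higher by 0.31 (adjusted p = 0.00308) and 0.25 (adjusted p = 0.00560). Whether these control probe sets, here and below, follow ribosomal RNA in the cells or the preparation of the samples was not tested. Heat shock genes also fell, 8 of 9 and 8 adjusted over the list alone, among them the chaperones HSPH1 (−0.58), HSPE1 (−0.47), HSPD1 (−0.45) and HSP90AB1 (−0.34) (camera adjusted p = 1.27e-05; adjusted p = 0.147 with an estimated correlation). Of 14 genes of cholesterol synthesis, 8 fell, and 8 when adjusted over the list alone, including the enzymes HMGCS1 (−0.67), SQLE (−0.66), MSMO1 (−0.46) and IDI1 (−0.36) (camera adjusted p = 0.00465; adjusted p = 0.404 with an estimated correlation).

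The cytotoxic granule and mitotic lists also passed in KHYG1, both upwards, while most or many of their members did not pass one by one. Of 17 granule genes, 8 rose and 1 fell (9 and 2 adjusted over the list alone), with granzyme H (GZMH) at 0.88, granzyme B (GZMB) at 0.59 and the cystatin CST7 at 0.51 beside GNLY (camera adjusted p = 0.000230; adjusted p = 0.430 with an estimated correlation). Of 30 mitotic genes, 10 rose and 0 fell, the same numbers as adjusted over the list alone, with small changes such as 0.28 for the kinesin KIF20A and 0.24 for the kinesin KIF2C (camera adjusted p = 0.000230; adjusted p = 0.404 with an estimated correlation). Among 17 immediate early genes 8 fell and 2 rose, also when adjusted over the list alone. ATF3 (−1.02), FOS (−0.80) and MYC (−0.51), transcription factors induced early by growth or stress signals, were lower and FOSL2 (0.65) was higher. The immediate early call was marginal (camera adjusted p = 0.0295; adjusted p = 0.404 with an estimated correlation), and was lost without array 1 labelled PRDM1α of KHYG1 (adjusted p = 0.0543) or without the filter (adjusted p = 0.0572).

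The other lists did not pass in KHYG1. Camera adjusted p was 0.187 for the interferon response, checkpoint and exhaustion, oxidative phosphorylation and T cell marker lists, and 0.305 for IL2 and JAK-STAT signalling. It was 0.582 for homing and adhesion, 0.602 for the BCL2 family, 0.780 for cytokines and chemokines, 0.796 for DNA replication, lymphocyte transcription factors, NF-kB targets, MHC class II, NK receptors, the p53 response, glycolysis and plasma cell markers, and 0.838 for the unfolded protein response and secretion. Some of these lists moved in opposite ways inside: 8 of 31 interferon response genes rose and 6 fell (9 and 7 adjusted over the list alone), and 6 of 25 lymphocyte transcription factors rose while 7 fell (6 and 7 adjusted over the list alone). For cytokines and chemokines the median change was 0.0098 and the mean −0.22. The signs of median, mean and test also differed for the DNA replication, lymphocyte transcription factor, NK receptor, unfolded protein response, glycolysis and plasma cell lists, none of which passed.

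In NK92, JCHAIN and RCAN2 again had the largest rises in the arrays labelled PRDM1α, 4.57-fold for JCHAIN (log2 change 2.19, SE 0.23, limma adjusted p = 6.13e-06) and 3.26-fold for RCAN2 (1.70, SE 0.14, adjusted p = 4.10e-07). JCHAIN started from 2.73, below the 10th percentile of the arrays, so the size of its rise is uncertain. CD160 had the largest measured fall, 5.60-fold (−2.48, SE 0.19, adjusted p = 2.55e-07), from 6.32 ± 0.13 to 3.84 ± 0.014 (SD, n = 2). GPR84, a receptor for medium-chain fatty acids, fell 5.04-fold (−2.33, SE 0.20, adjusted p = 8.82e-07), TRIM22, an interferon-induced ubiquitin ligase, 4.67-fold (−2.22, SE 0.17, adjusted p = 3.34e-07), and TNFSF14 4.59-fold (−2.20, SE 0.13, adjusted p = 9.67e-09). XCL1 fell 4.49-fold (−2.17, SE 0.055, adjusted p = 6.04e-13). CD160 at 3.84 and GPR84 at 3.58 ended close to the floor, so the sizes and the order of the largest falls are uncertain.

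Other large rises in NK92 were in SNAP47 (1.38), PLXNA1 (1.29), SPP1 (1.25), the cholesterol exporter ABCG1 (1.24), CCNG2, an atypical cyclin linked to cell cycle arrest (1.21), ZYG11B (1.19), ARAP3 (1.04) and TFEB, a transcription factor for lysosomal genes (1.01). IL18R1, a chain of the interleukin 18 receptor (−2.11), IL1RN, the interleukin 1 receptor antagonist (−1.92), HEG1 (−1.76) and CRYBG1 (−1.76) fell. As the same rule required, both arrays labelled PRDM1α lay beyond both empty-vector arrays for each of these genes. In all, 1243 genes passed, 599 higher and 644 lower, against 2404 at an unadjusted p under 0.05, and 62 changed at least 2-fold, 11 higher and 51 lower. Higher genes outnumbered lower ones under quantile normalization (730 and 605) and median centring (680 and 629). The count depended on single arrays. It was 786 without array 1 and 755 without array 2 of empty vector, and 781 without array 2 labelled PRDM1α.

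The lymphocyte transcription factor list was lower in the arrays labelled PRDM1α of NK92, with 14 of 25 genes lower, 2 higher and the same numbers adjusted over the list alone. IRF4, needed for plasma cell and effector lymphocyte differentiation (−1.10), BATF3 (−1.01) and the Ikaros-family factor IKZF2 (−0.54) were lower, and the list also holds PRDM1 itself as read by its brightest probe set (camera adjusted p = 1.73e-07; adjusted p = 0.108 with an estimated correlation). Ribosome biogenesis genes fell here too, 12 of 25 and 17 adjusted over the list alone, by a median of −0.21, with NIP7 at −0.36 and DDX21 at −0.30 (camera adjusted p = 3.62e-07; adjusted p = 0.108 with an estimated correlation). Of 5 ribosomal RNA control probe sets 4 were higher in the same arrays, by 0.38, 0.65 and 1.14 for the 3′ part, middle and 5′ part of 18S (adjusted p = 0.0408, 0.00154 and 8.64e-05) and by 0.39 for the 5′ part of 28S (adjusted p = 0.00113), while the middle of 28S measured 0.0046 (adjusted p = 0.978). Of 31 interferon response genes 9 fell and 0 rose (11 and 1 adjusted over the list alone), among them the antiviral genes IFIT3 (−1.30) and IFI44L (−1.18) and the exonuclease ISG20 (−1.11) beside TRIM22 (camera adjusted p = 2.52e-05; adjusted p = 0.108 with an estimated correlation).

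Further lists passed downwards in NK92, each with members that did not pass and most with some that rose. Of 15 cytokines and chemokines 8 fell and 2 rose (8 and 4 adjusted over the list alone). Interferon gamma (IFNG), the main NK effector cytokine, changed by −0.98, the inhibitory cytokine IL10 by −1.31 and IL16 by −0.60, beside XCL1 (camera adjusted p = 8.60e-05; adjusted p = 0.161 with an estimated correlation). Among 24 IL2 and JAK-STAT genes 7 fell and 2 rose (8 and 3 adjusted over the list alone), with the signal transducers STAT4 (−1.32) and STAT6 (−0.98), MYC (−0.52) and the kinase PIM1 (−0.43) lower (camera adjusted p = 0.00111; adjusted p = 0.193 with an estimated correlation). Among 17 immediate early genes 6 fell and 2 rose (7 and 3 adjusted over the list alone), with the nuclear receptor NR4A2 at −1.39, ATF3 at −1.02 and FOS at −0.65 (camera adjusted p = 0.0171; adjusted p = 0.193 with an estimated correlation). Among 9 checkpoint and exhaustion genes 4 fell, also when adjusted over the list alone, with CD160 and TOX (−0.56), a factor of exhausted T cells (camera adjusted p = 0.0411; adjusted p = 0.193 with an estimated correlation). The checkpoint call was lost under quantile normalization (adjusted p = 0.0570), median centring (0.0734) and no filter (0.0895), and without array 2 of empty vector (0.0582) or array 2 labelled PRDM1α (0.0788) of NK92.

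The list of the unfolded protein response and secretion passed upwards in the arrays labelled PRDM1α of NK92, with 7 of 25 genes higher and 0 lower (10 and 0 adjusted over the list alone), with asparagine synthetase (ASNS) at 0.38 and the endoplasmic reticulum chaperone calreticulin (CALR) at 0.34 (camera adjusted p = 0.000924; adjusted p = 0.184 with an estimated correlation). Of 27 DNA replication genes 6 rose by small amounts and 0 fell, the same as adjusted over the list alone (camera adjusted p = 0.00134; adjusted p = 0.108 with an estimated correlation). The helicase subunit MCM2, at 0.23, had the smallest p of that list, and its call was lost without array 1 of empty vector (adjusted p = 0.133) or array 1 labelled PRDM1α (0.113). Glycolysis (camera adjusted p = 0.0614) and heat shock (0.0675) did not pass. Both passed without array 1 (0.0488 each) or array 2 (0.0491 each) of empty vector of KHYG1. Glycolysis also passed without array 1 of empty vector of NK92 (0.0291) and with the replicate number as a block (0.0478). Further lists that did not pass were the BCL2 family (0.0762), T cell markers and cholesterol synthesis (0.141 each), MHC class II (0.160), mitosis (0.172), oxidative phosphorylation (0.400), the p53 response (0.461), homing and adhesion (0.516), NK receptors (0.633), NF-kB targets (0.638), plasma cell markers (0.664) and cytotoxic granules (0.669). Medians of the NK receptor, NF-kB and homing lists lay slightly above 0 while their means and tests pointed down.

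**Figure D2:**
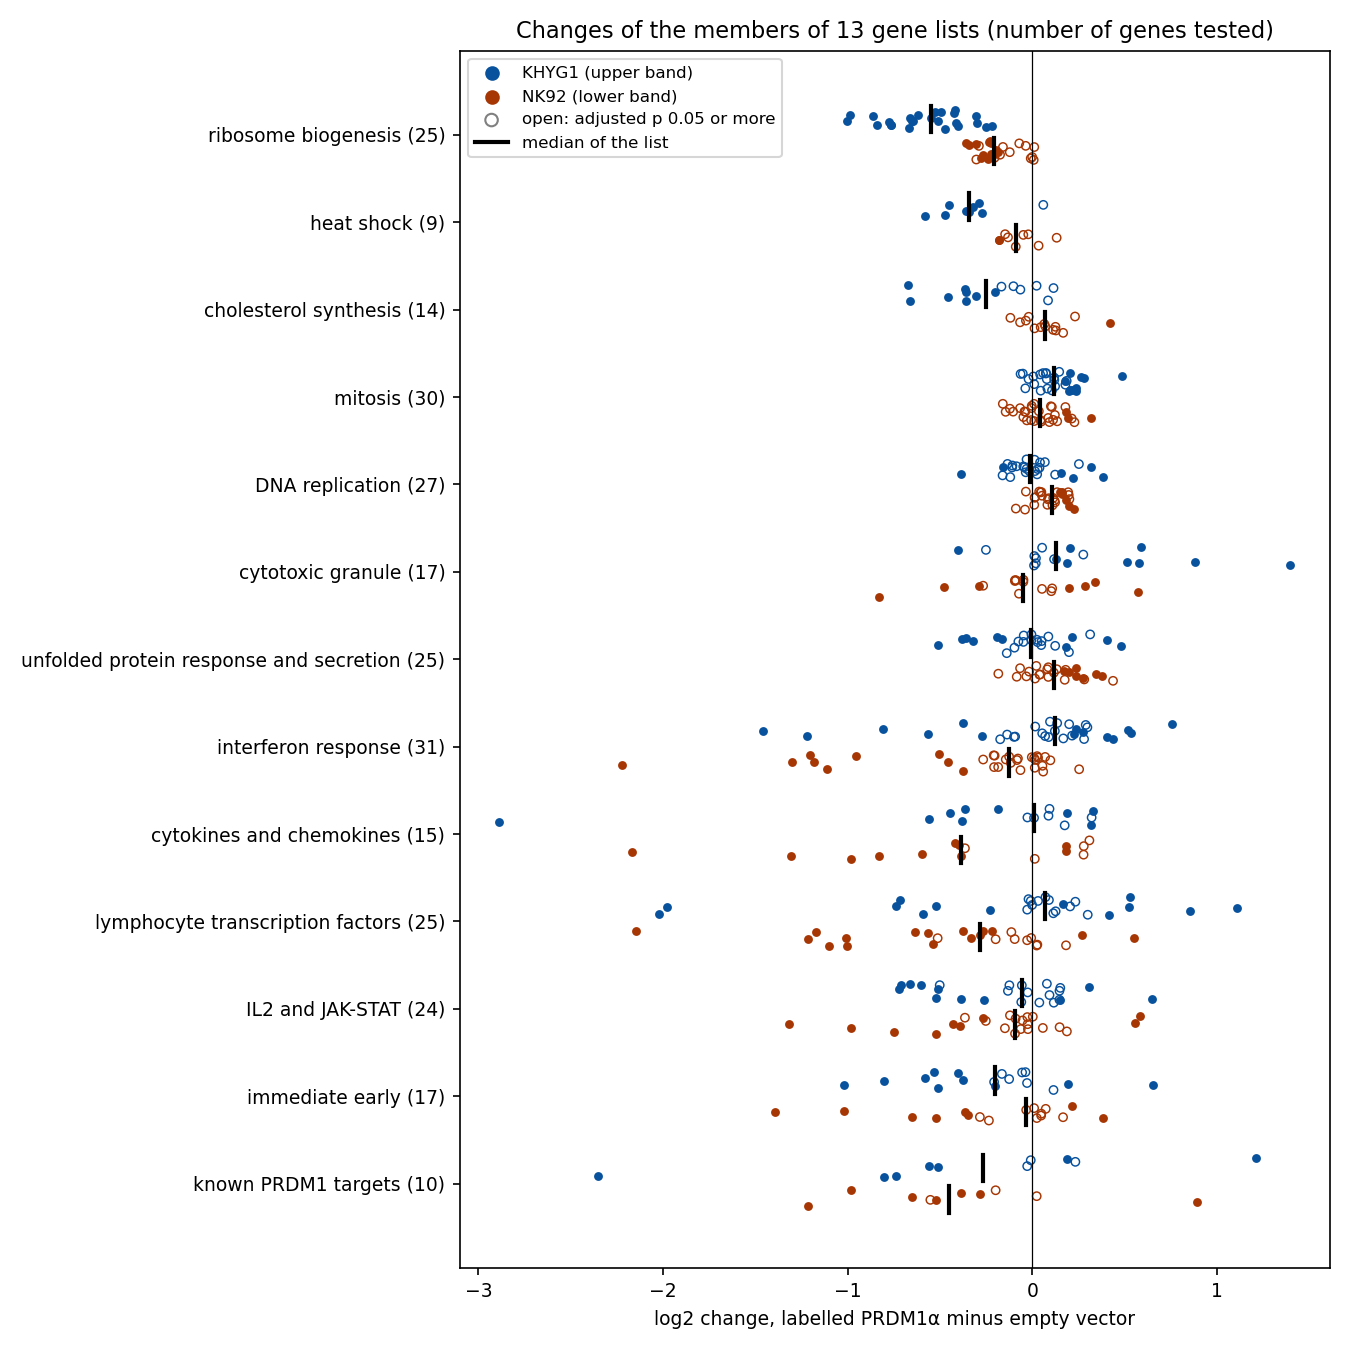
Log2 change (horizontal axis, arrays labelled PRDM1α minus empty vector) of each tested member of 13 gene lists (vertical axis, number tested in brackets) in KHYG1 and NK92; filled points passed the adjusted p of 0.05, open points did not, and black bars are list medians. The ribosome biogenesis list has its median at −0.55 in KHYG1 and −0.21 in NK92.

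Genes described earlier as direct PRDM1 targets, which PRDM1 represses in B, T or NK lymphocytes, were listed to ask whether they fell. Of 14 such genes 10 were tested. Of these, 5 fell and 2 rose in KHYG1, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.218). In NK92, 6 fell and 1 rose (7 and 1 adjusted over the list alone) with a median of −0.45 (camera adjusted p = 3.05e-05; adjusted p = 0.161 with an estimated correlation). MYC fell by nearly the same amount in both lines, −0.51 and −0.52, and FOS fell by 0.80 and by 0.65 on the log2 scale. PAX5, the B cell identity factor that PRDM1 represses in plasma cells, rose in both lines, by 1.21 in KHYG1 and by 0.89 in NK92. TNF fell in KHYG1 (−0.56) and in NK92 (−0.39), where the call was lost without array 1 of empty vector (adjusted p = 0.0698) or array 1 labelled PRDM1α (0.0901).

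CCR7 fell in KHYG1, and its change of −0.55 in NK92 did not pass (adjusted p = 0.0989). The repressor ID3 fell in NK92 by 1.21 on the log2 scale and measured −0.027 in KHYG1. IFNG rose slightly in KHYG1 (0.19, adjusted p = 0.00539) and fell in NK92 (−0.98, adjusted p = 1.04e-09). For these 3 genes the difference between the lines itself passed (IFNG adjusted p = 6.64e-08, CCR7 0.00129, ID3 0.00580). BACH2 fell in KHYG1 by 0.74 on the log2 scale, a call lost without array 2 of empty vector (adjusted p = 0.0936) or array 1 labelled PRDM1α (0.0625), and measured 0.024 in NK92. A second, dimmer probe set of BACH2 fell by 1.05 on the log2 scale in KHYG1 (adjusted p = 0.000819 over all named probe sets), past the threshold in every fit that left out an array. CIITA, which drives MHC class II expression and did not pass the filter, changed by −0.95 in NK92 (adjusted p = 0.00106 over all named probe sets) and by −0.20 in KHYG1 (adjusted p = 0.441). TBX21, the T-bet gene, fell in NK92 by 0.28 on the log2 scale, a call lost without array 2 of empty vector (adjusted p = 0.10) or array 1 labelled PRDM1α (0.0866), and measured −0.0081 in KHYG1. BCL6 did not pass in either line (0.23 and −0.20). These directions take the labels as given, which the brightest PRDM1 probe set goes against.

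Changes in the lines were alike for many genes. Across 9029 genes the log2 changes in KHYG1 and NK92 correlated with Pearson r = 0.487 and Spearman rho = 0.453, and genes are not independent replicates. The lines shared no arrays, and with NK92 changes shuffled among genes of similar spread the highest r of 100 simulations was 0.0394. Of the genes that passed, 298 were higher in both lines (71.98 for independent lists; up to 98 in the simulations; Fisher's exact test, odds ratio 9.61, p = 4.25e-126) and 370 were lower in both (112.1 for independent lists; up to 148 in the simulations; odds ratio 8.07, p = 1.00e-127). Among the 715 genes past the threshold in both lines, 668 moved the same way and 47 in opposite ways. The shuffling breaks up genes that move together, and Fisher's test counts genes as independent. Neither therefore covers a chance shift of whole groups of genes in both lines.

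**Figure D3:**
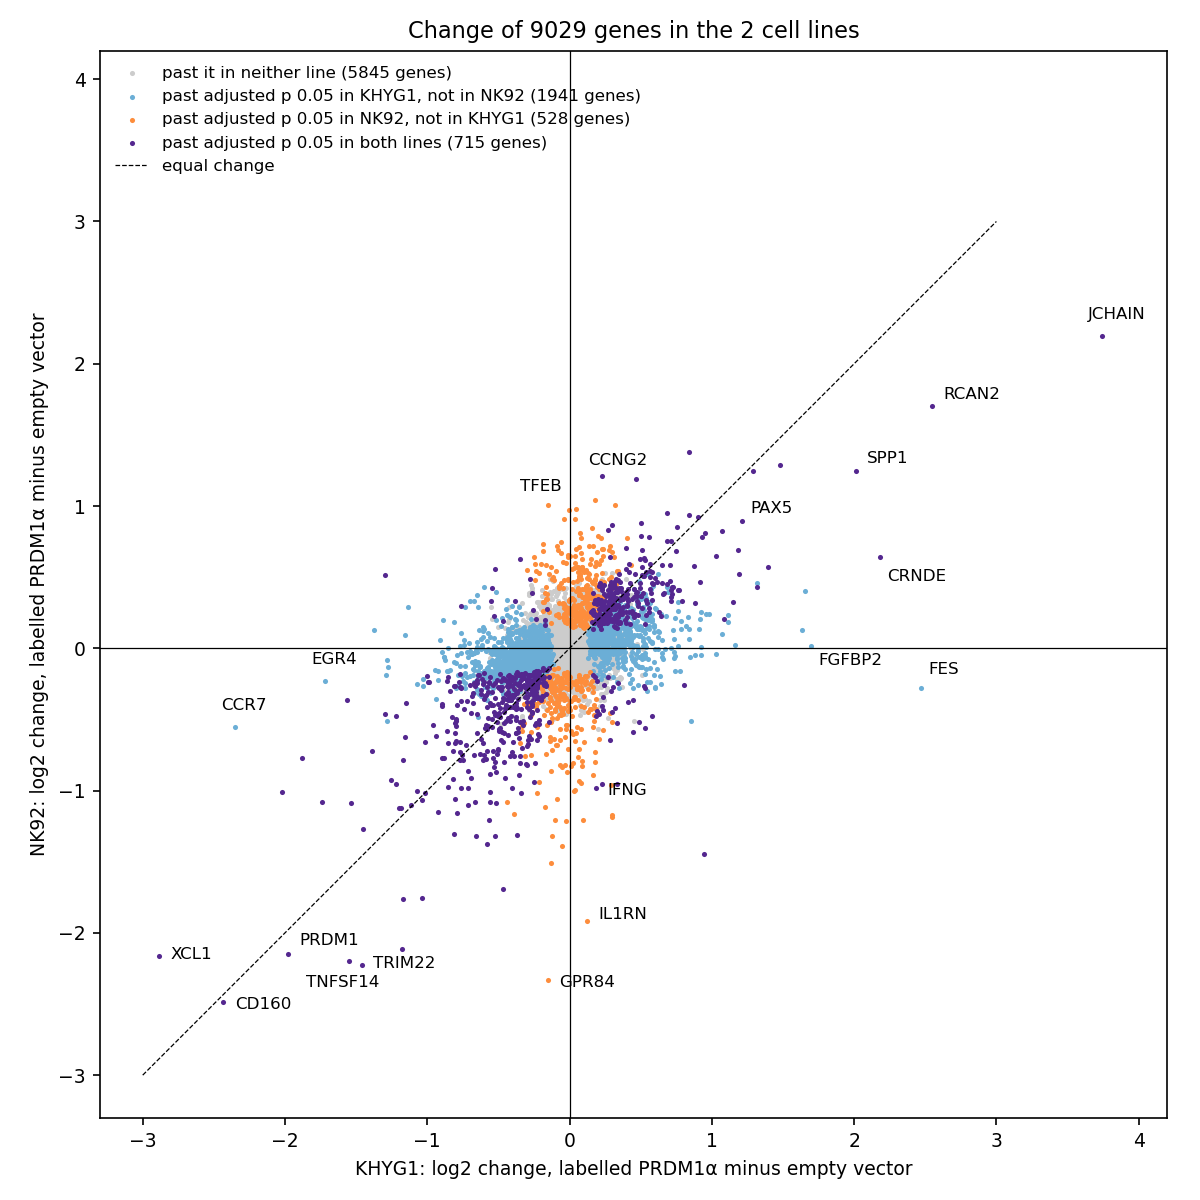
Log2 change of 9029 genes in KHYG1 (horizontal axis) and NK92 (vertical axis), arrays labelled PRDM1α minus empty vector; colours mark genes past an adjusted p of 0.05 in both lines (715), in one line or in neither, and the dashed line marks equal change. JCHAIN lies at 3.74 and 2.19, XCL1 at −2.89 and −2.17.

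In the fit of the change common to both lines, the largest rises in the arrays labelled PRDM1α were in JCHAIN (log2 change 2.97, SE 0.28, limma adjusted p = 2.43e-05), RCAN2 (2.13, SE 0.16, adjusted p = 3.82e-06) and SPP1 (1.63, SE 0.14, adjusted p = 1.07e-05). They were followed by CRNDE (1.41), PLXNA1 (1.38), ABCG1 (1.27), SNAP47 (1.11), PAX5 (1.05), FXYD2 (1.03) and GNLY (0.99). The largest falls were in XCL1 (−2.53, SE 0.11, adjusted p = 1.25e-07), CD160 (−2.46, SE 0.14, adjusted p = 8.82e-07), PRDM1 itself by its brightest probe set (−2.06), TNFSF14 (−1.87), TRIM22 (−1.84), IL18R1 (−1.64), BATF3 (−1.51), HEG1 (−1.47), CCR7 (−1.45) and SLAMF8 (−1.41). At least 1 group of JCHAIN, CRNDE and TRIM22 lay below the 10th percentile of its arrays, and CD160 and CCR7 ended near it, which limits the ranking. In this fit 1992 genes passed, 890 higher and 1102 lower, against 3264 at an unadjusted p under 0.05, and 36 changed at least 2-fold, 9 higher and 27 lower. That balance turned under quantile normalization (1185 higher and 985 lower) and median centring (1136 and 1023). Taking the mean of both lines' contrasts with the spread of the 4-group fit instead gave 3019 genes.

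Of the lists, ribosome biogenesis fell in the common change, 21 of 25 genes (23 adjusted over the list alone), with NIP7 at −0.39, NOP58 at −0.37 and DDX21 at −0.57 (camera adjusted p = 3.05e-12; adjusted p = 0.415 with an estimated correlation). Of 9 heat shock genes 5 fell (7 adjusted over the list alone), among them HSP90AB1 at −0.26 and DNAJA1 at −0.25 (camera adjusted p = 0.00279; adjusted p = 0.472 with an estimated correlation). Mitotic genes passed as a list with 2 of 30 higher, also when adjusted over the list alone (camera adjusted p = 0.00437; adjusted p = 0.415 with an estimated correlation). The known PRDM1 targets had 4 of 10 lower and 1 higher, 5 and 1 adjusted over the list alone (camera adjusted p = 0.0105; adjusted p = 0.415 with an estimated correlation). Immediate early genes had 6 of 17 lower and 2 higher, 9 and 2 adjusted over the list alone (camera adjusted p = 0.0144; adjusted p = 0.415 with an estimated correlation). IL2 and JAK-STAT genes had 8 of 24 lower and 2 higher, also when adjusted over the list alone (camera adjusted p = 0.0466; adjusted p = 0.472 with an estimated correlation), a call lost when any single NK92 array was left out (adjusted p from 0.0672 to 0.0947). The lymphocyte transcription factor list did not pass (camera adjusted p = 0.0534; adjusted p = 0.541 with an estimated correlation). It passed under quantile normalization (0.0387), median centring (0.0469) and no filter (0.0487) and without any single KHYG1 array (0.00993 to 0.0128).

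Where the lines differed was tested directly, as the NK92 change minus the KHYG1 change. IFNG differed most clearly, by −1.17 (SE 0.064, limma adjusted p = 6.64e-08). NBAS, a vesicle transport gene, rose in KHYG1 and differed by −1.50 (SE 0.092, adjusted p = 1.70e-07). The stress-induced gene PHLDA1 (−0.88), TC2N (−1.18) and SH2D1A, the adaptor SAP of NK activation (−0.97), were also lower in NK92 relative to KHYG1. ADAP1 (1.2, SE 0.086, adjusted p = 1.22e-06), the antiviral membrane protein IFITM1 (0.84), CCNG2 (0.98), the cyclin CCND2 (0.70) and the fatty acid desaturase SCD (0.76) differed the other way. In all, 819 genes passed, 486 with the higher change in NK92 and 333 with the lower, against 2078 at an unadjusted p under 0.05. The count was 375 without the intensity trend, and 539 without array 2 of empty vector of KHYG1, 509 and 515 without array 1 or 2 of empty vector of NK92, and 510 without array 2 labelled PRDM1α of NK92.

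Ribosome biogenesis genes fell less in NK92 than in KHYG1, with a median difference of 0.40. The difference passed for 15 of 25 genes (20 adjusted over the list alone), among them NOLC1 (0.65) and RRS1 (0.81), and for none downwards, with 0 (camera adjusted p = 3.34e-14; adjusted p = 0.0606 with an estimated correlation). The 18S ribosomal RNA control probe sets, given above, were higher in the arrays labelled PRDM1α of NK92, while in KHYG1 they changed by −0.026 to 0.097 with adjusted p of 0.722 or more. The 2 NK92 arrays with empty vector themselves measured 10.08 and 10.64 for the 5′ part of 18S. A change of ribosomal RNA in the cells is therefore not shown by these probe sets. Cholesterol synthesis genes also differed upwards, 7 of 14 (9 adjusted over the list alone), with HMGCS1 at 0.64 and SQLE at 0.54 (camera adjusted p = 1.02e-06; adjusted p = 0.102 with an estimated correlation). For heat shock genes the numbers were 5 of 9 and 7 adjusted over the list alone (camera adjusted p = 2.80e-05; adjusted p = 0.0970 with an estimated correlation). Unfolded protein response genes differed upwards in 5 of 25, 6 adjusted over the list alone (camera adjusted p = 0.0121; adjusted p = 0.306 with an estimated correlation), a call lost without array 1 labelled PRDM1α of NK92 (adjusted p = 0.0844).

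Other lists differed downwards. The change of 11 of 31 interferon response genes was lower in NK92 than in KHYG1 (16 adjusted over the list alone), among them IFI44L (−1.48) and ISG20 (−0.94) (camera adjusted p = 8.40e-10; adjusted p = 0.0606 with an estimated correlation). Most genes of this list were dimmer in KHYG1 under empty vector, with MX1 at 3.48, close to the floor. A fall of such genes could hardly be measured there, so the floor may give part of this difference. TRIM22 still fell in KHYG1, from 4.42 to 2.96. Of 17 cytotoxic granule genes 8 differed downwards and 1 upwards (9 and 1 adjusted over the list alone), with GZMH at −0.93 and GZMB at −0.69 (camera adjusted p = 4.39e-07; adjusted p = 0.285 with an estimated correlation). Of 25 lymphocyte transcription factors 11 differed downwards and 3 upwards (13 and 4 adjusted over the list alone), among them IKZF3 (−0.93), EOMES (−0.79), which directs NK maturation, and NFIL3 (−0.79), needed for NK development (camera adjusted p = 1.29e-06; adjusted p = 0.0970 with an estimated correlation). Of 15 cytokines 4 differed downwards and 1 upwards (5 and 2 adjusted over the list alone), with the chemokine CCL4 at −0.74 beside IFNG (camera adjusted p = 0.0225; adjusted p = 0.330 with an estimated correlation). Mitotic genes differed downwards in 3 of 30, 4 adjusted over the list alone (camera adjusted p = 0.00905; adjusted p = 0.329 with an estimated correlation). The mitotic call was lost under fry (fry adjusted p = 0.121). The glycolysis list passed with 0 of 18 genes past the threshold in either direction (camera adjusted p = 0.0407; adjusted p = 0.334 with an estimated correlation), and that call was lost under quantile normalization (adjusted p = 0.222), median centring (0.0521) and no filter (0.0807). Under fry the glycolysis call was lost as well (fry adjusted p = 0.138). It was also lost without array 1 of empty vector (0.0891) or array 2 labelled PRDM1α (0.0921) of KHYG1, and without array 2 of empty vector (0.0863) or array 2 labelled PRDM1α (0.0678) of NK92.

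The difference between the lines did not pass for the lists of DNA replication (camera adjusted p = 0.0537), IL2 and JAK-STAT signalling (0.0615), MHC class II (0.128), known PRDM1 targets (0.166), plasma cell markers (0.361), NK receptors and oxidative phosphorylation (0.372 each) and the BCL2 family (0.673). The same held for immediate early genes, homing and adhesion and T cell markers (0.856 each), NF-kB targets and checkpoint and exhaustion (0.924 each) and the p53 response (0.966). DNA replication did pass, upwards, under quantile normalization (0.0331) and no filter (0.0310) and under fry (0.00552). It also passed without array 1 of empty vector (0.0322) or array 1 labelled PRDM1α (0.0438) of KHYG1 or array 2 labelled PRDM1α of NK92 (0.0395). IL2 and JAK-STAT signalling passed without array 1 of empty vector of KHYG1 (0.0442).

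The lines themselves differed far more than the treatments. Under empty vector, 7310 genes passed, 3735 higher in NK92 and 3575 lower, and 2346 of them differed at least 2-fold, 1020 higher and 1326 lower. Among the largest measured excesses in NK92 was that of the junction protein TJP1 (log2 difference 7.66, SE 0.11, limma adjusted p = 8.41e-18), followed by the interferon-induced genes IFI27 (7.46) and MX1 (7.32), the collagen COL5A2 (7.22), OVAAL (6.92), MAP3K13 (6.83), the chemokine CCL18 (6.66), the cytokine receptor chain CSF2RB (6.59), LRRN3 (6.37) and SNX7 (6.28). Among the largest measured deficits was that of the RNA helicase DDX3X (−8.87, SE 0.15, adjusted p = 4.65e-17), followed by HMGN3 (−8.26), PEG10 (−7.70), the mitotic kinase PBK (−7.34), SDCBP (−7.26), ESD (−7.15), PLAC8 (−7.13), the T and NK cell coreceptor chain CD8A (−7.10), the calcium-binding protein S100A4 (−6.97) and OAT (−6.85). In 11 of these 20 genes the dimmer line lay below the 10th percentile of its arrays, with DDX3X at 2.35 in NK92 and TJP1 at 2.75 in KHYG1, so the sizes and the order of these differences are set in part by the floor. The arrays labelled PRDM1α do not enter these log2 differences, but they do enter the choice of probe set, the filter, the SE and the p-values. The difference between the 3′ and 5′ control probe sets of GAPDH, a sign of RNA or cRNA length, was 0.34 to 0.45 in the arrays of KHYG1 and 0.97 to 1.03 in those of NK92.

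Interferon response genes were higher in NK92 under empty vector, 28 of 31 with 2 lower, among them IFIT3 (4.12) beside IFI27 and MX1 (camera adjusted p = 1.11e-08; adjusted p = 0.0959 with an estimated correlation). Ribosome biogenesis genes were higher, 23 of 25 with 1 lower, among them NOP16 (2.10) (camera adjusted p = 2.32e-06; adjusted p = 0.229 with an estimated correlation). Glycolysis genes were lower, 16 of 18 with 1 higher, among them ALDOC (−4.80) (camera adjusted p = 4.51e-05; adjusted p = 0.229 with an estimated correlation). Mitotic genes were lower in 21 of 30 and higher in 3, with the centromere histone CENPA at −1.96 (camera adjusted p = 0.00182; adjusted p = 0.397 with an estimated correlation). Immediate early genes were lower in 11 of 17 and higher in 5, with the transcription factor EGR1 at −5.26 (camera adjusted p = 0.0321; adjusted p = 0.397 with an estimated correlation). Unfolded protein response genes were higher in 17 of 25 and lower in 6, the latter with ASNS at −5.76 (camera adjusted p = 0.0321; adjusted p = 0.397 with an estimated correlation). Cytotoxic granule genes were higher in 12 of 17 and lower in 4, with GNLY at 5.74 (camera adjusted p = 0.0321; adjusted p = 0.533 with an estimated correlation), a call at 0.0502 under quantile normalization. For all lists of this comparison the counts adjusted over the list alone were the same. IL2 and JAK-STAT genes (17 higher and 7 lower of 24) and cytokines (11 higher and 4 lower of 15, with CCL4 at 5.53) passed narrowly (camera adjusted p = 0.0412 and 0.0453; adjusted p = 0.397 with an estimated correlation in both) and were lost under median centring (0.0565 and 0.0670), quantile normalization (0.0502 each) and no filter (0.0616 each, the cytokine median going from 1.04 to 0.24).

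Markers of other cell types that a sorted culture could hold were also read. Of 8 B cell markers only PAX5 was bright enough to be tested. CD79A, CD22 and MS4A1 measured between 3.25 and 4.76 in every array. Of the plasma cell markers, 4 were tested, and JCHAIN rose while IRF4 fell in both lines. XBP1 changed by −0.36 in KHYG1, a call lost without array 2 of empty vector (adjusted p = 0.103) or array 1 labelled PRDM1α (0.0550), and by −0.084 in NK92 without passing. MZB1 changed by 0.50 in NK92, a call lost without array 2 of empty vector (0.164) or array 2 labelled PRDM1α (0.154), and by 0.29 in KHYG1 without passing. Among markers not tested, IGKC stayed between 4.99 and 5.39 and TNFRSF17 between 2.57 and 3.01. Of 7 T cell markers tested, LAT (0.27) and CD3E (0.35) rose in KHYG1, the CD3E call being lost without array 1 or 2 of empty vector (adjusted p = 0.0726 and 0.0732) or array 2 labelled PRDM1α (0.25). In NK92, CD6 (0.55), CD8A (0.48) and LAT (0.22) rose and CD28 (−0.66) fell. Of these, CD6 passed in every fit that left out an array. CD8A, which started near the floor at 3.23, was lost without array 1 of empty vector (adjusted p = 0.0738) or array 2 labelled PRDM1α (0.115) of NK92. CD28 was lost without the same arrays (0.123 and 0.0726). LAT in NK92 was lost without any single NK92 array (0.0773 to 0.125). Of the myeloid markers 2 were tested. ITGAM measured 0.36 in NK92, past the threshold but not when any single NK92 array was left out (adjusted p up to 0.162, without array 1 labelled PRDM1α). S100A9 measured −0.41 in KHYG1, past the threshold but not without array 2 of empty vector (adjusted p = 0.314) or array 2 labelled PRDM1α (0.369) of KHYG1, nor without any single NK92 array (0.0521 to 0.0534). PEG10, the only 293T packaging cell marker tested, changed by 0.23 in KHYG1 and 0.0058 in NK92 without passing, and none of the erythroid markers was tested, with 0 of 6.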

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

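The tests that bear on the PRDM1 probe sets and on the ribosome biogenesis list were chosen only after the result was seen.

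Results differed between the lines when the interaction term (NK92 change minus KHYG1 change) was tested. Among the largest changes in either line, the difference was −1.55 for JCHAIN, −0.84 for RCAN2, −2.75 for FES, −1.54 for CRNDE, −0.76 for SPP1, −1.68 for FGFBP2, −1.25 for FXYD2, −1.50 for NBAS and −0.82 for GNLY, all of which rose in KHYG1. For genes that fell in KHYG1 it was 0.72 for XCL1, 1.8 for CCR7, 1.01 for BATF3, 1.11 for DENND11, 0.67 for SLAMF8, 1.48 for EGR4, 1.2 for ADAP1 and −0.65 for TNFSF14. For genes that rose in NK92 it was 0.54 for SNAP47, 0.98 for CCNG2, 0.72 for ZYG11B, 0.86 for ARAP3 and 1.16 for TFEB. For genes that fell in NK92 it was −2.18 for GPR84, −0.93 for IL18R1, −2.04 for IL1RN, −0.59 for HEG1 and −0.72 for CRYBG1. The smallest p of this test also took in IFITM1 (0.84), CCND2 (0.70), SCD (0.76), IFNG (−1.17), PHLDA1 (−0.88), TC2N (−1.18) and SH2D1A (−0.97). JCHAIN under empty vector in both lines, CRNDE under empty vector in KHYG1 and GPR84 in the KHYG1 arrays labelled PRDM1α lay below the 10th percentile of their arrays, so these differences are uncertain in size. Close to the floor in both groups of one line were IL1RN in KHYG1 (3.41 and 3.53), FGFBP2 in NK92 (3.35 and 3.36) and EGR4 in NK92 (3.74 and 3.51). CCR7 ended near it in KHYG1 (3.50). The differences of these genes are uncertain in size as well, and a fall near the floor could hardly be measured. With the mean of all probe sets of a gene, the difference did not pass for XCL1 (adjusted p = 0.147) or CCND2 (adjusted p = 0.130).

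Lists past the threshold of the same interaction term had median differences of 0.40 for ribosome biogenesis, −0.11 for mitosis, −0.23 for cytotoxic granules, −0.042 for cytokines and chemokines, −0.26 for the interferon response, −0.31 for lymphocyte transcription factors, 0.15 for the unfolded protein response, −0.085 for glycolysis, 0.33 for cholesterol synthesis and 0.32 for heat shock. All of these calls were lost with an estimated correlation (adjusted p from 0.0606 to 0.334). For the interferon response the floor may give part of the difference, since members such as MX1 lay close to it in KHYG1.

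Signal also changed in probe sets that the comparisons did not use. Of 2203 tested probe sets with no single gene name, 513 passed in KHYG1 and 190 in NK92. Among control probe sets for ribosomal RNA, the changes past the threshold in NK92 were 0.38, 0.65 and 1.14 for the 3′ part, middle and 5′ part of 18S and 0.39 for the 5′ part of 28S. In KHYG1 they were 0.31 for the 5′ part and 0.25 for the middle of 28S.

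The brightest PRDM1 probe set was lower in the arrays labelled PRDM1α in both lines. An exchange of labels in both lines would put the known PRDM1 targets higher in those arrays, while in the common change 4 of 10 were lower, 5 did not pass and 1, PAX5, was higher (camera p = 0.00174, adjusted p = 0.415 with an estimated correlation). The list thus goes against an exchange in both lines at the preset correlation. Under fry, which does not compare it with other genes, it was lower in the common change (adjusted p = 0.00728), KHYG1 (0.0233) and NK92 (0.00357). Most lists passed under fry in each line, among them the p53 response (fry adjusted p = 0.0260 in KHYG1 and 0.0298 in NK92), which camera did not call. The fry passes are therefore not particular to the known targets. Camera did not call it in KHYG1 alone (camera adjusted p = 0.218). Probe sets that read different stretches of the transcript, of which the construct carries only some, could give the pattern, since the middle and the brightest probe set moved apart by 2.10 in KHYG1 and by more in NK92. This cannot be told apart from other explanations, because the change of the middle probe set in KHYG1 (0.12) did not pass and the positions of the probe sets were not used here. A fall of the cell's own PRDM1 transcript under the transgene may therefore be read from the brightest probe set only as a hypothesis, and it was not tested further.

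Ribosome biogenesis genes fell further in KHYG1 (median −0.55) than in NK92 (−0.21). The size of the response in NK92 over that in KHYG1, as a ratio of root mean square changes less error variance, was 0.327 for the list (95% bootstrap interval over genes 0.260 to 0.405). Genes were resampled as if independent and the arrays kept fixed, so these intervals hold no spread between arrays. The list also had the smallest camera p of all lists for the difference, which its low ratio restates. The comparisons that follow therefore hold for these arrays only. A response weaker in NK92 for all genes alike, for instance from less transgene, is argued against as the whole cause by the ratio of 0.821 (0.782 to 0.862) over the other 9004 genes, and by the 242 of their 804 genes past the threshold of the difference whose change was larger in NK92. Compression of bright signal in NK92 is argued against as the whole cause by the ratio of 0.709 (0.627 to 0.800) over 930 other genes as bright in NK92 as the list's median and brighter than in KHYG1. Either could account for a part, since both ratios lie below 1, and a response of ribosome biogenesis that differs between the lines stays open, untested beyond this.

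Grouping by chance was weighed for the change common to both lines. Of 34 splits of the 8 arrays into 4 and 4, with line as a covariate, only 1, the real one, gave as many as 1992 genes, and the highest of the others gave 0. Of the other splits only 1 kept the replicates of each group together, and it left the treatment difference common to both lines in the error. The rest divided at least 1 pair of replicates, which puts group differences into the error. A low count was thus close to fixed for the other splits, so they do not exclude chance. They also do not bear on chance differences between the groups of cells themselves.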

How the results depend on the processing

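The crossed pairing was chosen after seeing the data, and the other alternatives were planned. Counts of genes stayed within 1.5 times, and list and gene directions were kept, except as follows, and the cause was not tested unless stated. Requiring a 2-fold change left 68 genes in KHYG1, 62 in NK92, 53 for the difference, 36 for the common change and 2346 between the lines, by construction. The difference gave 375 genes without the intensity trend and 1255 at an adjusted p under 0.1, the latter by its wider threshold. The common change gave 3019 as the mean of both contrasts, which leaves the line-by-treatment differences out of its error. The correlation between lines was 0.519 with the larger amount added before the logarithm, 0.418 with no filter and 0.537 with the filter at the 60th percentile. With the replicate number as a block the difference gave 517 and the common change 1112, and only the common IL2 and JAK-STAT list changed a list call downwards (adjusted p = 0.0501). Same-numbered arrays deviated from their group means with r = −0.124 in KHYG1 and −0.158 in NK92, and arrays of the same number across the lines with r = 0.0704 for empty vector and 0.166 for PRDM1α. With 2 numbers and no pairing in the labels, the numbers were taken only as names. Crossed pairing gave 3037, 1515, 1068, 1498 and 7452 genes for KHYG1, NK92, the difference, the common change and the lines. Directions reversed for PAX5 in the difference (0.42 with that amount added), for PGK1 in KHYG1 (−0.041 with the mean of probe sets) and, under fry, for the lymphocyte transcription factor list in KHYG1, whose median was 0.072 while fry pointed down (adjusted p = 0.0158). Leaving out 1 array gave 1873 to 2631 genes in KHYG1, 755 to 1304 in NK92, 509 to 644 for the difference, 1359 to 1794 for the common change, 6822 to 7348 between lines and r from 0.459 to 0.476. In NK92 the count was 786 or 755 without empty-vector array 1 or 2 and 781 without array 2 labelled PRDM1α, and the difference gave 539 without KHYG1 empty-vector array 2, 509 or 515 without NK92 empty-vector array 1 or 2, and 510 without NK92 array 2 labelled PRDM1α. A group left with 1 array was assumed to vary like the others. All 41 list calls were lost with an estimated correlation, 39 held under fry, 37 under median centring, 36 under quantile normalization and 36 with no filter. The 2 lost under fry were mitosis and glycolysis in the difference between the lines. Of the 79 list tests without a call, 39 passed under fry in the direction of camera and 1, the lymphocyte transcription factor list in KHYG1, in the other. Of the same tests, 1 passed under median centring, 2 under quantile normalization, 2 with no filter and 1 with the block. Of 473 gene calls named in the text or lists, 63 were lost in at least 1 fit that left out an array. Without the intensity trend 64 of these 473 gene calls were lost, and 36 were lost with the replicate number as a block. With the mean of probe sets 42 of those still tested were lost. Dim genes limit precision, since replicate SD was 0.148 below a signal of 6 and 0.0460 above 10.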

Other observations

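The gene families here, and the search for genes bright in one line, were chosen only after the values were seen, while the tests on the bright genes were set before their results, except the count of those without another probe set.

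Among the families tested in KHYG1, 3 families had the smallest p among those lower in the arrays labelled PRDM1α. Of 14 cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, 12 fell and 0 rose, with LARS1 at −0.55, IARS1 at −0.50 and TARS1 at −0.50 (camera adjusted p = 3.45e-08 over 29 families; adjusted p = 0.0605 with an estimated correlation). In NK92, 0 of 14 fell and 1 rose (4 and 2 adjusted over the family alone), and the difference between the lines passed for 9 of 14 (camera adjusted p = 1.56e-08; adjusted p = 0.112 with an estimated correlation). Of 21 subunits of the mitochondrial protein import machinery, 16 fell in KHYG1, among them TIMM13 at −0.44 and TIMM17A at −0.36 (camera adjusted p = 6.32e-06; adjusted p = 0.0814 with an estimated correlation). Of 75 mitochondrial ribosomal proteins 30 fell and 1 rose, among them MRPL4 at −0.52 and MRPL12 at −0.50 (camera adjusted p = 1.01e-05; adjusted p = 0.291 with an estimated correlation). The import and mitochondrial ribosomal families also passed in NK92, with 1 of 21 and 6 of 75 genes lower (camera adjusted p = 0.0225 each; adjusted p = 0.262 and 0.534 with an estimated correlation), calls lost without array 2 of empty vector of NK92 (adjusted p = 0.0744 and 0.105). The import call was also lost without NK92 array 2 labelled PRDM1α (0.0564), and the mitochondrial ribosomal one without NK92 array 1 labelled PRDM1α (0.0629) and under quantile normalization (0.0510). In KHYG1 the medians of these 3 families were lower under quantile normalization and median centring too, and no call was lost when any array was left out. Cytosolic ribosomal proteins did not pass in KHYG1, with 4 of 29 lower and 0 higher and a median of −0.043 (camera adjusted p = 0.431), nor did the oxidative phosphorylation list, as given above.

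Some families of receptors and interferon-induced genes passed, and others did not. Inhibitory and activating KIR receptors of NK cells were higher in the arrays labelled PRDM1α, 10 of 11 in KHYG1 and 5 of 11 in NK92, with KIR3DL3 at 1.18 and 0.69 (camera adjusted p = 7.60e-08 and 0.00134; adjusted p = 0.0605 and 0.156 with an estimated correlation). All of these probe sets share sequence between relatives, so which KIR gene moved is uncertain. They may repeat the same signal, so the counts and the camera p-values, which treat them as separate genes, are uncertain too. The interferon-induced membrane proteins IFITM1, IFITM2 and IFITM3 fell in KHYG1, by −1.30, −1.29 and −0.995, and each fell further there than in NK92 (camera adjusted p of the difference 5.77e-06; adjusted p = 0.114 with an estimated correlation), with probe sets of IFITM2 and IFITM3 also shared. The camera p of this family is uncertain for the same reason. Of 4 interferon-induced IFIT genes, 3 fell in each line (camera adjusted p = 0.00737 in KHYG1 and 6.57e-05 in NK92; adjusted p = 0.142 and 0.143 with an estimated correlation). Of the GIMAP GTPases, which act in lymphocyte survival, 5 of 6 fell in NK92, with GIMAP7 at −0.56 (camera adjusted p = 6.57e-05; adjusted p = 0.143 with an estimated correlation), while in KHYG1 2 of 6 fell and the family did not pass (adjusted p = 0.235). TNF superfamily ligands and receptors (camera adjusted p = 0.633 in KHYG1 and 0.520 in NK92) and guanylate binding proteins (0.235 and 0.314) passed in neither line. Interleukin receptors did not pass in KHYG1 (0.263), and in NK92, with 5 of 17 lower and 2 higher, they passed (0.0214; adjusted p = 0.451 with an estimated correlation) but not without array 2 of empty vector (0.0511). Among them, both chains of the interleukin 18 receptor were lower in both lines, IL18R1 by −1.18 in KHYG1 and −2.11 in NK92, and IL18RAP by −1.45 and −1.27. Of the YPEL family, 4 of 5 rose in KHYG1 and 3 of 5 in NK92, with YPEL5 at 0.71 and 0.76 (camera adjusted p = 0.00297 and 0.0214; adjusted p = 0.118 and 0.262 with an estimated correlation), a call lost in NK92 without array 2 of empty vector (adjusted p = 0.0511).

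Some genes were bright in one line and near the floor in the other, whatever the vector. Above 9 in all 4 arrays of one line and below 4.5 in all 4 of the other were 30 genes, 20 bright in KHYG1, among them DDX3X, HMGN3, SDCBP and ESD, which most cells express, and 10 in NK92, among them TJP1, MX1 and CXCL8. Another probe set above the filter level was there for 14 genes, and 94.7% of those probe sets (18 of 19) differed by at least 1 log2 in the same direction. This argues against failure of a single probe set, for instance by a sequence variant of the line, for 13 of the 14, among them DDX3X, ESD and TJP1. The exception was RGS10, whose 1 other probe set did not differ in this way, so a failed probe set stays open for it. For the other 16 genes, among them HMGN3, SDCBP and MX1, no such probe set was there, so a failed probe set cannot be told apart from a true difference. Loss of a chromosomal stretch that spans neighbours may apply to some of them, since 28.3% of the nearest tested neighbours (17 of 60) differed the same way by at least 1 log2, against 12.99% of all tested genes in a given direction. That share lies between the bounds set for either outcome, so a loss cannot be told apart from silencing of single genes, which was not tested.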
